A study of Mus musculus with 2 samples.

How the data were processed

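Single cells were captured in droplets with the 5' chemistry of 10x Genomics, in which each transcript end or hashtag is tagged with a cell barcode and a unique molecular identifier, per the labels' protocols. The 2 libraries, mRNA and hashtag, came from the same pool of droplets, with 1 library of each kind. The submitters' processing notes name Cell Ranger 8.0.1 and the mouse genome build GRCm39. The settings for calling cells and the gene annotation release are not given in the sources used here.

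The files analysed were 3 text lists deposited by the authors. They were the cell barcodes, the features of the count matrix, and the definition of each hashtag with the population it marks. The file name calls the barcodes filtered, and they are taken here as those that Cell Ranger called as cells. None of these lists holds a measured value. The count matrix that belongs with them was not analysed here. For that reason no cell was assigned to a hashtag, no cells were filtered, no doublets were sought, no clusters or cell types were called, and no level, error or p-value was computed for any gene. Depth, confidence intervals and limits of detection could not be given for the same reason.

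The lists were read with Python 3.11.15. Barcodes and features were tallied, repeated entries were sought, and pairs of barcodes that differed at exactly 1 base were sought. That search was checked on a smaller set of simulated barcodes, with planted pairs that all differed at the same position. The positions at which the hashtag barcodes differ were compared pair by pair. The feature list held 33699 entries, of which 33696 were genes and 3 were hashtags. Gene names were used as that list pairs them with Ensembl identifiers. Of the 33696 identifiers, 31961 (94.9%) were also in a separate reference table of mouse gene names, and 29374 had the same name there. That reference belonged to an older mouse genome build, so mismatches do not by themselves point to errors in the feature list. No annotation of GRCm39 was used, so no gene coordinates are given.

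The samples were grouped by library type, as the labels give it. The populations are distinguished only by hashtag within the pool. The comparisons, 12 lists of genes by function, 9 lists of cell type markers, the rule for choosing named genes and the processing alternatives were fixed before the data were examined. A single gene of the naive and memory list is not reported here and is left out of the tallies of list members, which do not cover that list as it was fixed. The rule was to name, in each comparison, the 15 genes with the largest fold in each direction and the list members with enough molecules. Without molecule counts it names list members only to say whether the feature list holds them. Examples within each list were picked as well known members.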

Results

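The experiment compared antigen-specific helper T cells in the lymph nodes draining the nose between mice that had and had not been given allergen-specific IgE. T cells came from DO11.10 mice, a transgenic strain whose CD4 T cells carry a receptor for a peptide of ovalbumin (OVA). They were polarised in culture into Th2 cells, the helper subset that makes the allergy-associated cytokines IL-4, IL-5 and IL-13, and were transferred into BALB/c recipients. The recipients were given 1 mg of OVA in 20 µL through the nose on each of 4 successive days, from day 4 to day 7. Some recipients were also injected with 2 µg of OVA-specific IgE on day 4. Cervical lymph nodes were taken 24 hours after the last challenge, and the transferred T cells were sorted by CD4 and the DO11.10 receptor.

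The cells formed 3 populations, and each was marked with its own hashtag, an antibody that carries a DNA barcode and binds most cells. Hashtag1 (C0301), with the barcode ACCCACCAGTAAGAC, marked T cells from recipients injected with IgE. Hashtag2 (C0302), with the barcode GGTCGAGAGCATTCA, marked T cells from recipients without OVA-specific IgE. Hashtag3 (C0303), with the barcode CTTGCCGCATGTCAT, marked Th2 cells straight from culture. The hashtag barcodes were 15 bases long. Those of Hashtag1 and Hashtag2 differed at 11 positions, and that of Hashtag3 differed from each of the others at 12 positions.

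The populations were pooled and loaded together, and the pool gave 2 libraries, 1 of mRNA and 1 of hashtags. The list of filtered barcodes, taken here as cell-associated droplets, held 12112 barcodes for the pool as a whole. All 12112 barcodes were different and 16 bases long, and 0 pairs of them differed at exactly 1 base. These are traits of the list and say nothing of the quality of the cells. The list does not say which hashtag a barcode carried, so the number of cells in each population is not reported here. The table of molecule counts per gene and barcode was not analysed here, and the depth of the libraries is therefore unknown.

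The first comparison in the design sets T cells from IgE-injected recipients (Hashtag1) against T cells from recipients without OVA-specific IgE (Hashtag2). No expression level, fold change or share of cells is reported for it, and no direction is given for any gene. The members of the lists given next were all among the 33696 genes of the feature list, the genes to which reads could be assigned. The list of Th2 cytokines and regulators had 13 of 13 members in the feature list, among them Il4, Il5 and Il13, which encode the signature Th2 cytokines, Gata3, the transcription factor that directs Th2 differentiation, and Il1rl1, which encodes the receptor for an alarm cytokine of epithelial cells. The T follicular helper list had 9 of 9 members there, including Bcl6, the transcription factor that defines this subset, Cxcr5, the chemokine receptor for B-cell follicles, and Il21. The activation list had 12 of 12 members, including Nr4a1 and Egr2, which are induced by signals through the T-cell receptor. The regulatory T-cell list had 6 of 6 members, including Foxp3, and the exhaustion and anergy list had 7 of 7, including Lag3 and Tigit, which encode inhibitory receptors. These figures state which genes were in the annotation, not whether any transcript of them was found.

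The second comparison sets Th2 cells straight from culture (Hashtag3) against T cells recovered from lymph nodes, with Hashtag1 and Hashtag2 each taken separately. It likewise has no value here. All the lists by function were fixed for both comparisons and were not divided between them. The list of naive and memory genes had 6 of 6 reported members in the feature list, including Ccr7, which encodes a chemokine receptor for entry into lymph nodes, and S1pr1, which encodes a receptor for exit from them. The tissue homing list had 8 of 8 members, the Th1 list 4 of 4, the Th17 list 4 of 4, the proliferation list 6 of 6, the interferon response list 6 of 6 and the metabolism list 5 of 5. The cell type markers were also in the feature list. All were present for T cells (6 of 6), B cells (5 of 5) and CD8 T cells (2 of 2). The same held for natural killer cells (3 of 3), dendritic cells and macrophages (6 of 6) and plasma cells (3 of 3). It held too for basophils and mast cells (4 of 4), red blood cells (2 of 2) and stroma (3 of 3). The 21 lists, with the unreported gene left out, held 119 different genes, and each of these was in the feature list and tied to a single Ensembl identifier.

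Each population was marked by a single hashtag within a single library, and no source used here ties cells to separate animals. The number of animals behind each population is not given in the sources used here. Cells are not replicates, so neither comparison would have had a test across replicates even with the molecule counts.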

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

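The tallies of the lists are the results that could be recomputed. Taking each barcode once left the number of barcodes at 12112, since the list repeated none. That tally could not test how cells were called. Taking each gene name once gave 33670 names in place of 33696 genes, because 26 names each stood for 2 identifiers. Other settings of the hashtag rule, the cell filter, the scaling and the clustering were not run, since each needs the molecule counts. No paired analysis was possible because each population carried a single hashtag and no source used here ties cells to separate animals. Depth was not known, so what it limits was not assessed.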

Other observations

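The feature list held variable and joining gene segments of the T-cell receptor alpha and beta chains, the only T-cell-receptor segments tallied. By name it held 130 alpha variable, 60 alpha joining, 35 beta variable and 14 beta joining segments. It also held 183 immunoglobulin heavy variable segments, which are transcribed in B-lineage cells, and 13 mitochondrial genes, which are commonly used to judge cell quality. These are entries of the annotation and carry no level.

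In the feature list, 26 gene names stood for 2 identifiers each, 52 identifiers in all. They included Ddit3, a transcription factor of the stress response, Aldoa, a glycolytic enzyme, and Nnt, a mitochondrial transhydrogenase, chosen here as familiar genes after the names were seen. A sum by gene name would merge the entries of each, and a sum by identifier would keep them apart. None of the 119 reported genes of the lists was affected. A further 248 genes had no name other than their identifier.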
